A study of Canis lupus familiaris with 16 samples.

How the data were processed

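Genomic DNA from lymph node aspirates of 5 dogs with high-grade B-cell lymphoma and from blood mononuclear cells of 3 healthy dogs was captured for methylated DNA, and per the labels' protocols libraries were made from the captured DNA and sequenced as paired ends on an Illumina instrument. Each dog has a library labelled L and a library labelled M-H, 16 in all. Per the labels each library belongs to a peak group, and the authors deposited 1 peak list per peak group, so each list combines the dogs of a group; whether reads or called peaks were combined is not stated. BWA, MACS2 and the build CanFam3.1 are named in the submitters' processing notes, without versions, roles or settings. Per the file headers the lists give each peak's position, the fold enrichment (a ratio of reads in the peak to a background whose source is not stated), the gene assigned by the authors, the distance to its transcription start, and flags for CpG islands, shores, promoters and enhancers. The deposited fold enrichment is nowhere below 6 in any of the 4 lists, so peaks under 6 appear to have been left out before deposit. A locus without a peak can therefore hold methylated DNA with a lower enrichment. The lists hold no p-values, q-values, read counts or values per dog, so depth is unknown and a longer list can come from deeper sequencing or from more dogs.

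Peak starts were read as 0-based, since the length column equals end minus start, and are printed 1-based. In 4, 2 and 3 rows of the lymphoma L, healthy L and lymphoma M-H lists the gene columns were shifted, and these peaks were kept as intergenic. In the lymphoma L list 54 gene symbols had been turned into dates by a spreadsheet; 51 were restored from the gene description and 3 left out. The transcription start of each gene was recovered from the peak start and the distance to it. This gave 1 start for 18111 of 18147 symbols. Genes with no assigned peak in any list are not measured. Biotypes and names came from a RefSeq table of the UU_Cfam_GSD_1.0 assembly, matched by symbol for 15838 symbols (87.3%), and no coordinate was taken from it because the builds differ. This left 11410 named protein-coding genes.

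Peaks sharing at least 1 bp counted as shared. Shared shares were set beside 100 uniform random placements within chromosomes. A gene had a promoter peak where a peak overlapped the 1 kb either side of its transcription start, and was called both, lymphoma-only, healthy-only or neither within a fraction. Location was taken from the recovered starts (midpoint within 1 kb), then from the files' annotation. For 16 gene lists fixed before the data were examined, the number of lymphoma-only and healthy-only members was compared with 10000 random lists of named protein-coding genes of the same size. Matching on promoter CpG number was planned but needs a genome, which was not used here. The lists covered HOX genes, other developmental transcription factors, WNT antagonists, tumour suppressors, genes mutated in B-cell lymphoma, markers of B cells, T cells, natural killer cells, monocytes and granulocytes, and stroma and endothelium, germline, imprinted and housekeeping genes, DNA methylation enzymes, neuropeptides and neurotransmitter receptors, and cadherins. Their membership comes from textbook knowledge, not from these dogs. Counts and shares refer to measured members. Those not measured included 1 of 24 WNT antagonists, 11 of 39 HOX genes and 12 of 97 neuropeptide and receptor genes. They also included 20 of 32 natural killer and 26 of 50 monocyte and granulocyte markers.

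Genes named in the text follow a rule fixed before the data were examined. Per fraction it takes the 10 named protein-coding genes with the highest fold enrichment among lymphoma-only and among healthy-only promoters, and up to 4 one-group members of each gene list, with preference for genes called alike in both fractions. Genes named for a call in both fractions, for a promoter peak in both groups or for opposite calls, and the HOXD region, were chosen after their values were seen. A few genes that the rule takes are not reported here by name; they remain in the counts.

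The group of each library came from its label, and lymphoma was compared with healthy within L and within M-H, and L with M-H within each group. No test was run between groups, because each has 1 pooled list. Alternatives were another minimum overlap, another promoter window, a stricter threshold on fold enrichment, equal list lengths and a wider window for absence. Further ones were added after seeing the data: a fold enrichment of at least 8 in both lists, of at least 12 for the gene's own peak, the authors' own flag for a transcription start, and another background for the random lists. The overlap, promoter and list steps were tested on simulated data. Of 27345 planted shared peaks of the lymphoma L list 100% were found, 99.9% of 898 planted promoter calls were recovered, and 4% of 400 random gene lists lay outside the central 95% of percentiles. Planted peaks were placed so that they always reached their source peak or promoter window. The overlap and promoter results therefore check the code only, not the settings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.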

Results

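DNA methylation was profiled by MethylCap-seq, an assay in which fragments of methylated DNA are captured and sequenced, so that a peak of reads marks a methylated stretch of the genome. Tumour cells were aspirated from enlarged lymph nodes of 5 dogs with high-grade B-cell lymphoma, an aggressive cancer of B lymphocytes. Mononuclear cells from the blood of 3 healthy dogs served as controls. Each dog gave 2 libraries, labelled L and M-H, which makes 16 libraries; what these labels stand for is not given in the sources used here, and they are treated as separate fractions. The peaks were listed once per group and fraction, pooled over dogs. The lymphoma L list held 45623 peaks over 33.2 Mb and the healthy L list 44811 peaks over 26.7 Mb. The lymphoma M-H list held 34939 peaks over 27.9 Mb and the healthy M-H list 19867 peaks over 12.4 Mb. Read depth per library is unknown. With 1 pooled list per group there is no spread between dogs, so no test between groups was possible and each difference has no replicate check. Intervals are 95% Wilson intervals and cover counting error only. Disease and tissue went together in every sample, lymph node in the lymphoma group and blood in the healthy group.

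The first comparison asked which loci were methylated in lymphoma but not in healthy cells in the L fraction, and the reverse. Gene promoters carried a peak in the lymphoma list only far more often than in the healthy list only. Of 18147 genes, 2911 had a promoter peak in lymphoma only, 698 in healthy only and 2813 in both, so that lymphoma-only genes were 80.7% (79.3 to 81.9) of the one-group genes, a ratio of 4.17. Genes of neuropeptides and neurotransmitter receptors were frequent among the lymphoma-only promoters, and antagonists of WNT signalling were so under some settings. Promoters of B-cell identity genes and of genes recurrently mutated in B-cell lymphoma were rare among them. Relative to genes with a promoter peak in either group, none of these 4 lists was outside the central 95% of random lists. The mutated genes had too few such peaks to fall below it. The peaks as a whole were more evenly split: 28798 lymphoma peaks (63.1%, 62.7 to 63.6) overlapped a healthy peak and 16825 did not, while 29019 healthy peaks (64.8%, 64.3 to 65.2) overlapped a lymphoma peak and 15792 did not. Random placement of the peaks gave 2.63% and 2.68%.

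Lymphoma-only promoter peaks were ranked by fold enrichment in the lymphoma L list. Fold enrichment is the authors' own value for each peak and ranks peaks within a list; it is not compared between lists. DSC3, which encodes a desmosomal cadherin of epithelia, led with a fold enrichment of 21.9 for a peak at chromosome 7, 58412835 to 58413525 (CanFam3.1), annotated as coding sequence. SRRM3, a splicing regulator, followed at 21.2 (chromosome 6, 7426421 to 7427045, upstream annotation, spanning the transcription start). The intronic peaks of CALB1, a calcium-binding protein, and TPH1, the rate-limiting enzyme of serotonin synthesis outside the brain, each had 20.9. The peak of CALB1 lay at chromosome 29, 35572678 to 35573160, and that of TPH1 at chromosome 21, 40571397 to 40571991, both across the transcription start. SST, the gene of somatostatin, had 20.3 (chromosome 34, 20064054 to 20064883, intron). RPL17, NEMF, CPD, ADGB and JAKMIP2 completed the leading 10, with 19.6 to 21.1 (JAKMIP2 19.6, RPL17 21.1). The RPL17 peak ended 991 bp upstream of the transcription start, at the edge of the window.

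TCIM, a regulator of WNT signalling, led the healthy-only promoters of the healthy L list with 12.3 (chromosome 16, 25213124 to 25213514, coding sequence), followed by PDE6C, a phosphodiesterase of cone photoreceptors, with a peak in the 5' UTR (chromosome 28, 7839825 to 7840384). LRRC40 (11.8), LRRC1, SHB, IMMP2L, FOXJ3, PPRC1, ZNF135 and C6H1orf52 completed the leading 10. The peaks of SHB, LRRC40, C6H1orf52 and PPRC1 lay 945 to 997 bp from the transcription start, at the edge of the window. LRRC1 and IMMP2L were also healthy-only in M-H, whereas SHB was lymphoma-only there.

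Among the gene lists set before the data were examined, neuropeptides and neurotransmitter receptors stood furthest apart in L by the count of random lists. By the share of lymphoma-only members the WNT antagonists were higher (39.1% against 36.5%). Of 85 measured members, 31 had a promoter peak in lymphoma only, 2 in healthy only and 20 in both, and 0 of 10000 random lists of the same size held as many lymphoma-only genes (mean 14.5). Besides SST, OPRM1, the mu opioid receptor (17.7), and GLRA1, a glycine receptor subunit (17.5), were among the highest. Of 23 WNT antagonists, 9 were lymphoma-only, 1 was healthy-only and 3 were in both, and 104 of the random lists held as many lymphoma-only genes. They included the secreted inhibitors SFRP5 (13.4), SFRP4 (12.1) and WIF1 (8.54) and the intracellular inhibitor NKD1 (11.3). The SFRP5 peak lay in an intron at chromosome 28, 10998948 to 10999562. Of 33 imprinted genes, a class expressed from 1 parental allele, 11 were lymphoma-only, 1 was healthy-only and 4 were in both, with 170 random lists holding as many. ZDBF2 (12.7), SLC22A18 (11.3), L3MBTL1 (10.6) and NAA60 (9.19) had the highest values of the lymphoma-only imprinted genes. With a fold enrichment of at least 8 required in both lists, an alternative chosen after seeing the data, the WNT antagonists were at percentile 69.1 and the imprinted genes at 59.3 in L, and the germline genes at 99.6. This cut-off lies above the median fold of the healthy L list (7.77) and below that of the lymphoma L list (8.92), so it does not act alike on the lists. The WNT antagonists were at percentile 95.4 with absence required over 5 kb, and the imprinted genes at 92.3 with promoters of 500 bp either side. These percentiles describe the lists and are not p-values. The lists were not matched on CpG content. When random lists were drawn only from genes with a promoter peak in either group, a background chosen after seeing the data, 0 lists exceeded the central 95% in L, against 3 in the main comparison.

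B-cell markers and lymphoma genes had few lymphoma-only promoters in L, while T-cell, natural killer and myeloid markers lay near random lists. Of 32 B-cell markers, 1 was lymphoma-only, 3 were healthy-only and 1 was in both, and 197 of 10000 random lists held as few lymphoma-only genes (mean 5.44). The healthy-only members included POU2AF1, a transcriptional coactivator of B cells (9.41, 5' UTR, chromosome 5, 21671007 to 21671639), and SPI1, a transcription factor of B and myeloid cells (6.34). The lymphoma-only member was CD38, a surface enzyme of activated lymphocytes and plasma cells (13.5, coding sequence, chromosome 3, 64576151 to 64577214). Of 42 genes recurrently mutated or rearranged in B-cell lymphoma, 2 were lymphoma-only, among them SGK1 (9.85), and 39 had no promoter peak in either list. With promoters taken as 2 kb upstream to 500 bp downstream, the B-cell markers were at percentile 12.2 of random lists and the mutated genes at 3.66. With a fold of at least 8 in both lists they were at 3.0 and 3.23, so under either setting both lists were inside the central 95%. Both were also inside it when random lists were drawn only from genes with a promoter peak in either group, at percentiles 10.5 and 67.9. Only 3 mutated genes had such a peak, too few for that list to fall below the range. The low counts thus go with few promoter peaks of any kind in these lists. Of 37 T-cell markers, 7 were lymphoma-only and 2 healthy-only, near the random mean of 6.28. CD40LG (17.5), SH2D1A (15.3), CD8A (10.5) and CD8B (10.2) were the highest of the lymphoma-only members. The CD40LG peak, annotated as downstream of LOC100684432, ended 869 bp upstream of the CD40LG start (895 bp in M-H). TBX21 (11.1), a transcription factor of cytotoxic and helper T cells, and CD244 (7.00) were the 2 lymphoma-only genes among 12 natural killer and cytotoxic cell markers, none of which was healthy-only. Of 24 monocyte and granulocyte markers, 4 were lymphoma-only, FCGR1A (10.2), CD14 (9.16), VCAN (8.02) and C5AR1 (7.88), and 1 was healthy-only.

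The lymphoma-only counts of the other lists lay within the central 95% of random lists in L. Of 44 tumour suppressors known for promoter methylation, 7 were lymphoma-only, 0 healthy-only and 5 in both. CDH1, the epithelial cadherin, had 10.7, the matrix protease inhibitor TIMP3 10.1, the retinoic acid receptor RARB 8.20 and the death-associated kinase DAPK1 7.54. CDKN2A, TFPI2 and SOCS3 had a promoter peak in both groups. Of 28 HOX genes, 7 were lymphoma-only, 2 healthy-only and 6 in both, at percentile 86.1 of random lists. HOXD9 (9.40), HOXB13 (8.90) and HOXA13 (7.95) were lymphoma-only and HOXC12 (7.78) was healthy-only. With a fold of at least 8 in both lists the direction turned, with 2 lymphoma-only and 4 healthy-only HOX genes, the latter at percentile 99.9. These 4, HOXB4, HOXB6, HOXC13 and HOXD3, all had a lymphoma promoter peak with a fold below 8. The turn thus rests on fold values and not on absent peaks. Of 150 developmental transcription factors outside the HOX clusters, 19 were lymphoma-only and 6 healthy-only, and 120 had no promoter peak. DMRTA1 (11.4), NEUROG1 (10.0), LHX4 (9.96) and BNC1 (9.58) led its lymphoma-only members. With a fold of at least 8 in both lists 8 of the 150 were lymphoma-only, below the central 95% of random lists. Germline genes, which are silenced by promoter methylation in most somatic tissues, had a promoter peak in both groups for 37 of 59 members, and 7 were lymphoma-only, among them the meiotic genes MSH4 (15.0) and SPO11 (11.9). Of 25 stroma and endothelium markers, 4 were lymphoma-only and 2 healthy-only, with FLT4 (10.4) and COL1A2 (8.37) lymphoma-only and CDH5 (7.86) healthy-only. Of 23 protocadherins and cadherins, 4 were lymphoma-only, led by CDH7, and 3 were healthy-only, at percentile 97.6 of random lists; at a fold of at least 8 in both lists none was healthy-only. Among 18 DNA methylation and demethylation enzymes and readers, TET1 (9.83) was the lymphoma-only and TET3 (7.98) the healthy-only member, and 4 were in both. The TET1 peak lay 856 bp downstream of the start, annotated as an intron of LOC106558703, and the TET3 peak 751 bp downstream. With absence over 5 kb neither call held, as 0 members were lymphoma-only and 0 healthy-only. Of 40 housekeeping genes, 3 were lymphoma-only, FBL (13.8), SDHA (11.3) and REEP5 (6.47), and 0 healthy-only.

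The second comparison asked the same question in the M-H fraction, where nearly all one-group promoters belonged to lymphoma. There 3400 genes had a promoter peak in lymphoma only, 131 in healthy only and 1847 in both, so that lymphoma-only genes made up 96.3% (95.6 to 96.9) of the one-group genes, a ratio of 26.0. HOX genes, neurotransmitter receptors and WNT antagonists were frequent among the lymphoma-only promoters. Other developmental transcription factors were so too, but not with equal list lengths or with a fold of at least 8 in both lists. Relative to genes with a promoter peak in either group, of these 4 lists only the latter was above the central 95% of random lists. Of the lymphoma peaks, 17889 (51.2%, 50.7 to 51.7) overlapped a healthy peak and 17050 did not. Of the healthy peaks, 17964 (90.4%, 90.0 to 90.8) overlapped a lymphoma peak and 1903 did not. Random placement gave 1.26% and 2.20%. The lymphoma list was 1.76 times as long as the healthy list. With both lists kept to equal length by fold enrichment, 1911 genes were lymphoma-only and 513 healthy-only. This cut the lymphoma list at a fold of 9.32, so the 513 include genes whose lymphoma peak was removed.

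Lymphoma-only promoter peaks in M-H were ranked in the same way. WSB1, a substrate-binding part of a ubiquitin ligase, led with 21.9 (chromosome 9, 41868591 to 41869250). Its peak was annotated as an intron of LOC111097438 and ended 932 bp upstream of the WSB1 start. HPGD, which degrades prostaglandins, followed with 21.8 (chromosome 25, 24993097 to 24993746, intron). The adhesion gene CDH7 had 21.4 (chromosome 1, 11824088 to 11824671, intron). LGALS3, PRUNE2, VGLL3, SEMA3A, NLRP14 and NEMF had 20.4 to 21.2 (NEMF 20.4, LGALS3 21.2). Of these, LGALS3 and SEMA3A had a promoter peak in both groups in L. The healthy-only promoters were led by SLC25A5, a mitochondrial ADP/ATP carrier, with 10.4 (chromosome X, 91524017 to 91524505, intron), and ALYREF, an mRNA export factor, with 10.1 (chromosome 9, 397285 to 398078, upstream). CKAP4, ACO1, CYP26C1, MC1R, ODC1, EFNB3, PPIL6 and SMPD2 had 8.47 to 9.74 (CKAP4 9.74), and PPIL6 and SMPD2 shared 1 peak. The CKAP4 peak ended 997 bp upstream of the transcription start, at the edge of the window.

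Among measured members, HOX genes had the highest share of lymphoma-only promoters of all lists in the main M-H comparison (57.1%). Neuropeptides and neurotransmitter receptors followed (55.3%). This order rests on the measured members. Of all members fixed beforehand, 16 of 39 HOX genes and 47 of 97 neuropeptide and receptor genes were lymphoma-only, so the latter had the higher share. With equal list lengths neuropeptides and receptors also had the higher share of measured members (28 of 85 against 8 of 28). Of 28 HOX genes, 16 were lymphoma-only, 0 healthy-only and 3 in both, and 0 of 10000 random lists held as many lymphoma-only genes (mean 5.68). HOXB13 (13.0), HOXD9 (12.7), HOXD3 (11.5) and HOXA11 (11.3) had the highest values of the lymphoma-only HOX genes. Across the HOXD cluster on chromosome 36, from 19896185 to 20000326, the lymphoma M-H list had 14 peaks and the healthy M-H list 1, against 10 and 4 in L. Most of the 14 lay below a fold of 9.32, the lowest kept in the lymphoma M-H list with equal list lengths. That setting thus keeps only a minority of them. Of 150 other developmental transcription factors, 53 were lymphoma-only, 0 healthy-only and 5 in both, again with 0 of 10000 random lists holding as many. NEUROG1 (14.5), which specifies neurons, TFAP2B (12.7), SIX6 (12.6), a factor of eye development, and LHX4 (12.2), a factor of pituitary development, led its lymphoma-only members. With equal list lengths the lymphoma-only count of these factors was at percentile 28.1 of random lists. With a fold enrichment of at least 8 required in both lists, an alternative chosen after seeing the data, it was at percentile 28.3. The HOX genes were at percentiles 99.3 and 99.9 under these settings. With equal list lengths 8 HOX genes were lymphoma-only and 1 was healthy-only.

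**Figure D1:**
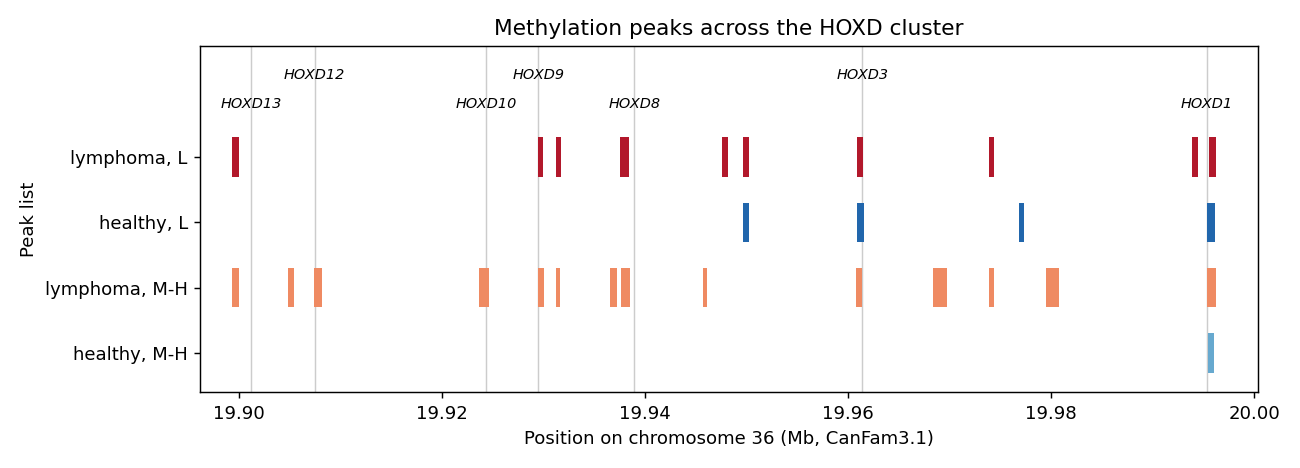
Map of the HOXD cluster on chromosome 36 (CanFam3.1, position in Mb), with each peak of the 4 lists drawn to scale as a box and each recovered transcription start as a vertical line. The lymphoma lists hold 10 (L) and 14 (M-H) peaks and the healthy lists 4 and 1. Most of the 14 lie below a fold of 9.32 and are not kept with equal list lengths. The region was chosen after its values were seen.

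Neuropeptides and neurotransmitter receptors were lymphoma-only for 47 of 85 members in M-H, healthy-only for 1 and in both for 11, with 0 of 10000 random lists holding as many lymphoma-only genes (mean 17.2). With equal list lengths 28 were lymphoma-only and 4 healthy-only, and again 0 random lists held as many lymphoma-only genes. SST (19.9), the serotonin receptor HTR1B (18.2) and the cannabinoid receptor CNR1 (18.1) were among the highest. Of 23 WNT antagonists, 11 were lymphoma-only, 1 was healthy-only and 1 was in both, and 29 random lists held as many. WIF1 had 17.7 (chromosome 10, 7725623 to 7726217, intron, across the transcription start), NKD1 14.6, SFRP5 12.9 and DACT2 12.4. NKD2, a relative of NKD1, was the healthy-only member (7.08) and was lymphoma-only in L (7.74). It was not healthy-only in M-H with promoters of 500 bp either side or 2 kb upstream to 500 bp downstream, nor with absence over 5 kb. With equal list lengths the WNT antagonists were at percentile 99.1 of random lists. When random lists were drawn only from genes with a promoter peak in either group, 1 list exceeded the central 95% in M-H, the developmental transcription factors outside the HOX clusters, against 4 in the main comparison.

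B-cell markers and lymphoma genes again had few lymphoma-only promoters in M-H. Of 32 B-cell markers, CD38 (17.0) was lymphoma-only, FCER2, the low-affinity IgE receptor of B cells, was healthy-only (8.43, intron, chromosome 20, 52459805 to 52460202), and 29 had no promoter peak. SGK1 (6.05) was the lymphoma-only member of the 42 genes recurrently mutated or rearranged in B-cell lymphoma, and 40 had no promoter peak. Of 10000 random lists, 59 held as few lymphoma-only genes as the B-cell markers and 11 as few as the mutated genes. With equal list lengths the B-cell markers were at percentile 5.9, and with 2 kb upstream to 500 bp downstream 4 mutated genes were lymphoma-only, at percentile 3.92, so neither call held under every setting. Among genes with a promoter peak both calls ended, with the B-cell markers at percentile 11.9 and the mutated genes at 29.8. Of 37 T-cell markers, 6 were lymphoma-only and 0 healthy-only, led by PRKCQ, a kinase of T-cell receptor signalling (15.7), CD40LG (15.4), CD8A (14.7) and CAMK4 (11.3). The natural killer list had 2 lymphoma-only members, NCAM1 (6.98) and TBX21 (6.60), of 12. The monocyte and granulocyte list had 3 of 24, FCGR1A (15.2), C5AR1 (11.1) and CD14 (9.75). Of 25 stroma and endothelium markers, 7 were lymphoma-only, led by FLT4 (16.3), the receptor of lymphatic endothelium, COL1A2 (9.90) and KDR (9.88).

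Of 44 tumour suppressors, 10 were lymphoma-only in M-H, 0 healthy-only and 4 in both, close to the random mean of 8.85. With equal list lengths 4 were lymphoma-only (random mean 5.07) and 1 was healthy-only. RARB (13.1), LOX (12.8), CDH1 (12.4) and CDKN2A (10.2), an inhibitor of cell cycle kinases, led the lymphoma-only members. Germline genes had 33 of 59 members in both groups and 10 lymphoma-only, led by TEX14 (17.5) and HORMAD1 (16.1). None was healthy-only, but with equal list lengths 6 were lymphoma-only and 9 healthy-only. That setting cut the lymphoma list at a fold of 9.32, while the healthy list kept peaks from 6. These 9 genes thus had a lymphoma promoter peak below the cut. With a fold of at least 8 in both lists 18 were lymphoma-only and 1 healthy-only, the former at percentile 99.5, so the alternatives went both ways. Of 33 imprinted genes, 11 were lymphoma-only, led by NDN (14.9), ZDBF2 (12.4), ASCL2 (8.86) and PEG10 (8.24), and 0 healthy-only. With equal list lengths 2 were lymphoma-only and 2 healthy-only, at percentile 17.3 for lymphoma-only. Of 23 protocadherins and cadherins, 7 were lymphoma-only, with CDH7, CDH10 (15.4) and PCDH1 (13.5) in front. TET1 (15.6), which oxidises methylated cytosine, was the lymphoma-only member of 18 DNA methylation enzymes and readers, and 3 were in both. Its peak lay 840 bp downstream of the start, annotated as an intron of LOC106558703. With promoters of 500 bp either side 0 of the 18 were lymphoma-only. Of 40 housekeeping genes, 2 were lymphoma-only, NONO (12.1) and REEP5 (7.50), and HPRT1 (6.08) was healthy-only. Of 10000 random lists, 66 held as few lymphoma-only genes (mean 8.06), so that few lymphoma-only promoters in M-H were not particular to B-cell and lymphoma genes. With a fold of at least 8 in both lists the housekeeping genes were at percentile 4.55, and among genes with a promoter peak at 4.04.

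**Figure D2:**
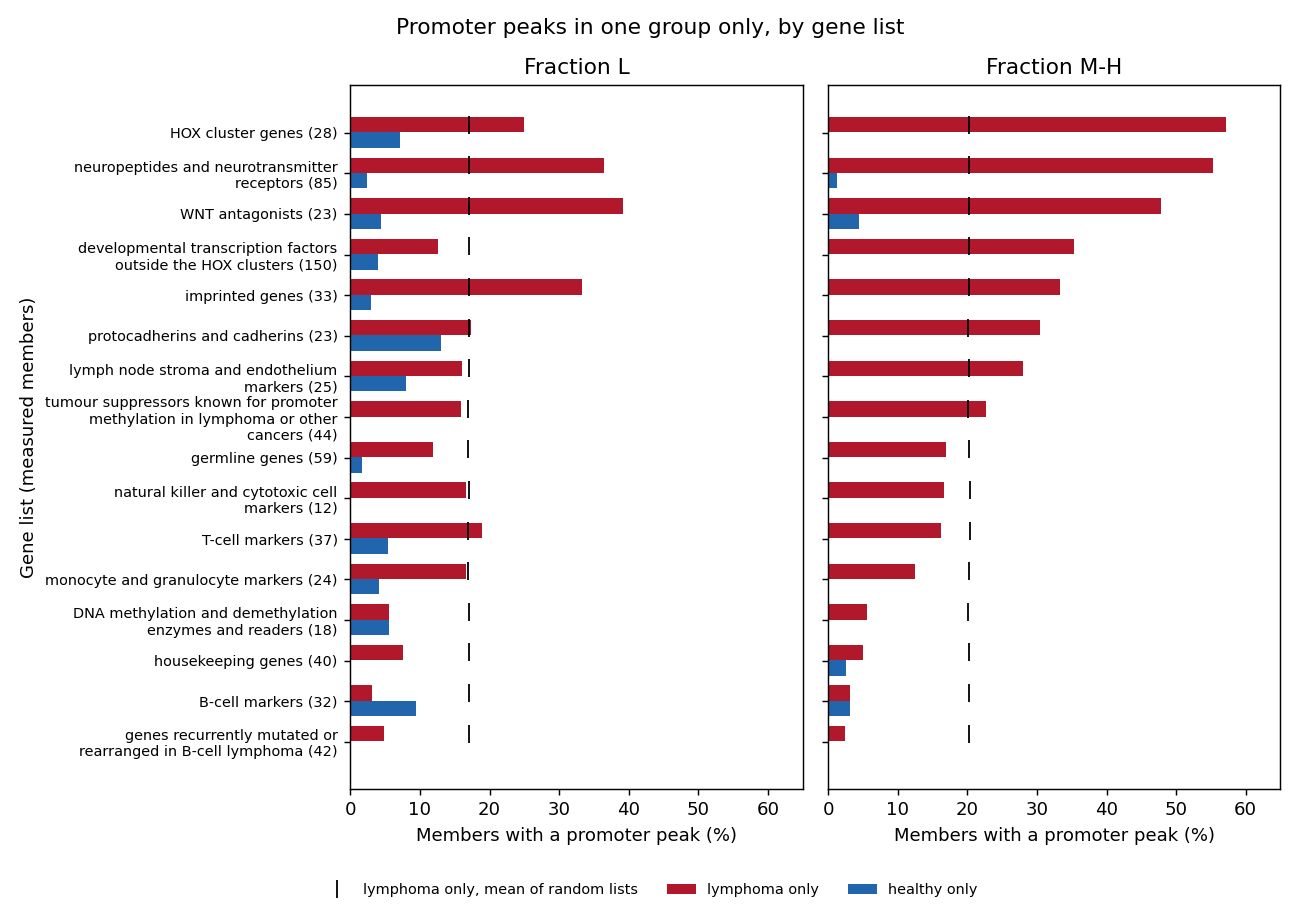
Percent of the measured members of each gene list with a promoter peak in lymphoma only or in healthy only, in the L and M-H fractions, with measured members in parentheses. Vertical ticks mark the mean lymphoma-only percent of 10000 random lists; HOX genes had 16 of 28 members lymphoma-only in M-H and neuropeptides and neurotransmitter receptors 47 of 85.

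The third comparison set the fractions beside each other within each group. In lymphoma, 63.2% (62.7 to 63.6) of L peaks overlapped an M-H peak and 82.1% (81.7 to 82.5) of M-H peaks overlapped an L peak. In healthy dogs these shares were 28.4% (28.0 to 28.8) and 63.3% (62.6 to 64.0). The genes called lymphoma-only coincided in part: of 2911 in L and 3400 in M-H, 1886 were so in both, against 545 for independent lists. Of the 3400, 889 had a promoter peak in both groups in L, against 527 for independent lists, and 43 were healthy-only there. HOXD3, SIX6, CDKN2A, TEX14, HORMAD1, NDN, KDR, CAMK4 and PCDH1, named above for M-H, were among these 889. Of the 2911, 406 had a promoter peak in both groups in M-H, against 296 for independent lists, and 15 were healthy-only there. The libraries of both fractions came from the same dogs, so the fractions are not independent. These 1886 genes included 26 of the neuropeptide and receptor list, 12 developmental transcription factors, 8 WNT antagonists, 8 imprinted genes and 6 HOX genes. WIF1, SFRP4, SFRP5, NKD1, DKK1, AXIN2, DACT1 and DACT2 were the WNT antagonists. Among tumour suppressors CDH1, RARB, DAPK1 and LOX were lymphoma-only in both fractions, and among T-cell markers CD8A, CD8B, CD40LG and PRKCQ. Healthy-only promoters were shared by 18 genes, against 5.04 for independent lists. SSTR1, a somatostatin receptor, was the 1 member of the gene lists among them. Opposite calls were made for 15 genes that were lymphoma-only in L and healthy-only in M-H, such as NKD2, and for 43 genes with the reverse, such as HOXC12, MSX2, ALX4 and MYOD1.

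The position of the peaks was compared next. In both fractions lymphoma peaks lay closer to promoters. In L, 10.4% of lymphoma peaks and 6.18% of healthy peaks had their midpoint within 1 kb of a transcription start, and in M-H 12.3% and 8.02%. Peaks found in lymphoma only were within 1 kb for 15.1% in L and 16.5% in M-H, and peaks found in healthy only for 3.76% and 5.94%. CpG islands, the CpG-dense stretches at many promoters, and their shores held 52.3% (51.6 to 53.1) of the lymphoma-only L peaks, 27.0% of the shared loci by the healthy list and 9.0% (8.57 to 9.46) of the healthy-only L peaks. In M-H they held 56.2% (55.4 to 56.9) of lymphoma-only peaks, 52.7% of the shared loci by the healthy list and 32.5% (30.5 to 34.7) of healthy-only peaks, so lymphoma-only and shared loci were far closer there than in L. Of all healthy-only L peaks, 44.7% lay in introns outside promoters, against 32.9% of all lymphoma-only L peaks. Exons outside promoters held 9.09% and 10.2%. The larger promoter share of the lymphoma-only peaks lowers their other shares. The island annotation on its own, without shores, covered 4.46% of lymphoma and 3.03% of healthy peaks in L but 8.30% and 13.7% in M-H.

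**Figure D3:**
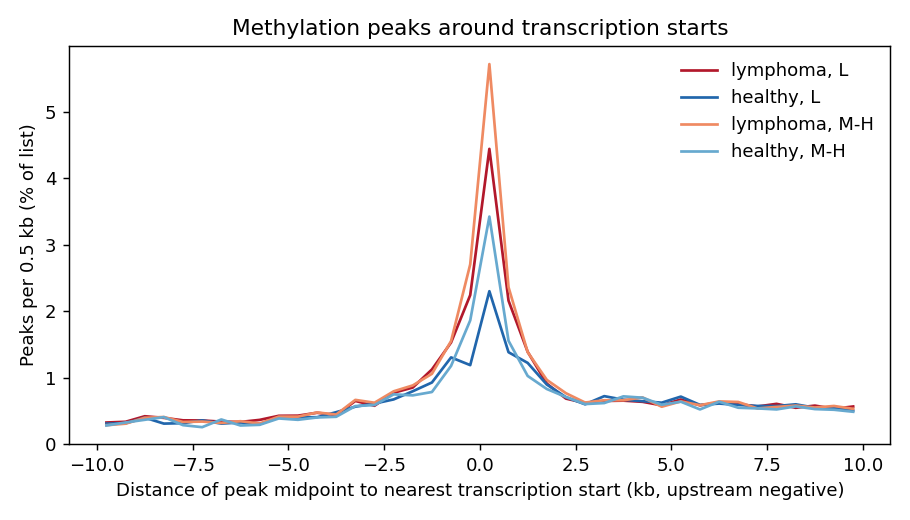
Percent of each list's peaks per 0.5 kb of distance between peak midpoint and nearest transcription start (kb, upstream negative), for the 4 lists. All lists are highest just downstream of the start, and within 1 kb lie 10.4% (lymphoma L), 6.18% (healthy L), 12.3% (lymphoma M-H) and 8.02% (healthy M-H) of peaks.

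**Figure D4:**
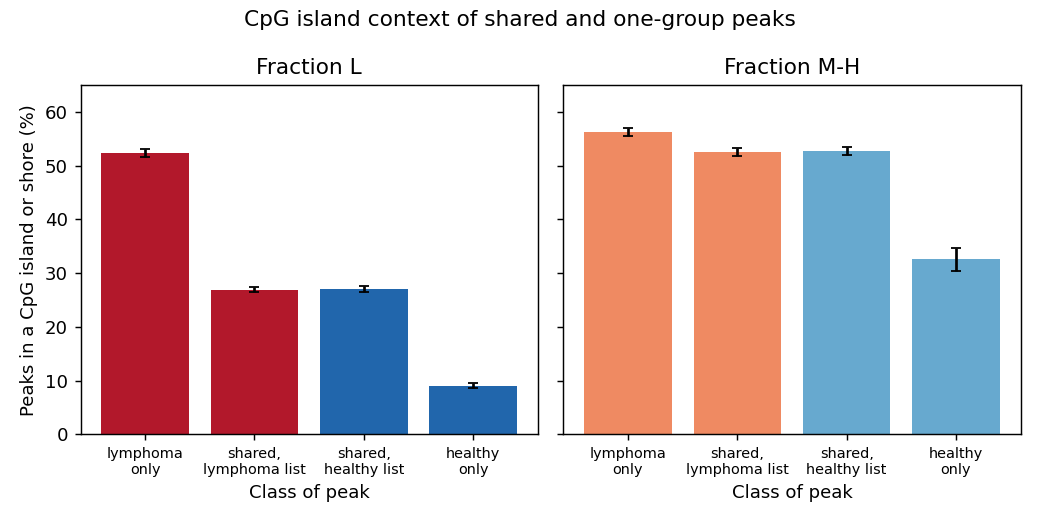
Percent of peaks in a CpG island or shore by class of peak in fractions L and M-H; bars are shares of the peaks of a class and error bars 95% Wilson intervals for counting error. Lymphoma-only peaks reach 52.3% in L and 56.2% in M-H, and healthy-only peaks 9.0% and 32.5%.

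No chromosome stood far from the rest. Relative to the ratio of all peaks, the lymphoma to healthy ratio of peak numbers ranged in L from 0.849 on chromosome 32 to 1.15 on chromosome 10, and in M-H from 0.848 on chromosome 19 to 1.20 on chromosome 30, over 39 chromosomes. Copy number changes of the tumours were not controlled for. Sex of the dogs was not controlled for either, which limits calls of genes on chromosome X, such as SLC25A5, HPRT1, NONO, CD40LG and SH2D1A.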

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

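The tests of peak width, of island methylation, of list length and of blood cell types were chosen after the results were seen; the test among peaks outside islands and shores was set before. The share of peaks in CpG islands alone differed between lymphoma and healthy in opposite directions in the 2 fractions: lymphoma minus healthy was 1.43 percentage points in L and -5.40 in M-H. The difference between the fractions was not tested, since each value comes from 1 pooled pair of lists. Less island methylation in lymphoma, as the reason for the M-H value, would lower the share in island or shore as well, and that share was 3.55 points higher in the lymphoma M-H list. Dependence of the island flag on peak width may account for the M-H value: at loci present in both M-H lists, 69.3% of healthy peaks marked as island had a lymphoma peak marked as shore, against 10.6% for the reverse, and the lymphoma peaks there were wider (median 989 against 649.5 bp). Membership of island or shore, without telling them apart, was equal at 99.9% of these loci. In L the flag differed in the same direction at shared loci, 51.0% against 13.0% (median widths 972 and 656 bp). Width would thus lower the lymphoma share in L too and does not account for the higher value there. In L 8.11% of lymphoma-only and 1.08% of healthy-only peaks were marked as island.

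Opposite calls between the fractions were made for 15 genes that were lymphoma-only in L and healthy-only in M-H, where independent lists would give 21.0, and for 43 genes that were healthy-only in L and lymphoma-only in M-H, where they would give 131. These differences between fractions were not tested. Genes of the latter kind included EPOR, the erythropoietin receptor, GDNF, a neurotrophic factor, and MYOD1, and those of the former KCNJ5 and NKD2.

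The excess of lymphoma-only over healthy-only promoters was weighed against a longer or deeper lymphoma list. With lists of equal length, the ratio of lymphoma-only to healthy-only peaks was 2.65 at flagged promoters and 0.937 in intergenic sequence in L, a quotient of 2.82 (2.60 to 3.07). In M-H the quotient was 3.50 (3.11 to 3.93). The difference in length was removed here, but depth was not equalised. In every list, peaks at or above the median fold lay at promoters more often than all peaks did. A deeper list need not gain both kinds of sequence alike, so a deeper lymphoma list stays open. Capture of more CpG-dense DNA in the lymphoma libraries could favour promoters too. Among peaks outside islands and shores the quotient was lower, 1.63 (1.44 to 1.86) in L and 1.95 (1.54 to 2.47) in M-H. In L the excess itself was absent there, with 497 lymphoma-only and 556 healthy-only peaks at flagged promoters. That ratio of 0.894 exceeded only the intergenic ratio of 0.547. In M-H 194 were lymphoma-only and 138 healthy-only, a ratio of 1.41 against 0.721 in intergenic sequence. The L interval of the quotient reaches below the bound of 1.5 set before, so capture of CpG-dense DNA stays open. Lymph node against blood as the source of cells also stays open, because 0 healthy samples came from lymph node. A tumour-specific gain of promoter methylation, the biological reading, cannot be told apart from these.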

How the results depend on the processing

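The alternatives with a fold enrichment of at least 8 or 12, the authors' flag, the other random background and the median threshold for location and chromosomes were chosen after seeing the data; the others were planned. Of 114 alternative values of the main results, 57 stayed within the counting interval or 1.5 times the main count and 57 did not, and in no case did lymphoma-only genes as a whole become fewer than healthy-only genes; where not stated, the cause was not tested. Of 320 alternative counts within single gene lists, 86 moved by more than 1.5 times. Within lists the direction turned for germline genes in M-H with equal lengths (6 lymphoma-only and 9 healthy-only), HOX genes in L at a fold of at least 8 (2 and 4) and stroma markers in L with absence over 5 kb (1 and 2). The germline and HOX genes counted as healthy-only there had lymphoma promoter peaks below the cut. No paired analysis was possible because the lists are pooled over dogs, and leaving out single dogs, a threshold on q and placements or lists matched on CpG density were not run, since the lists hold no such values and no genome was used. Unknown depth and the limit at a fold of 6 bound every statement on absence.

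Requiring 50% of the shorter peak moved no shared share beyond its interval. Within 500 bp, shares became 64.2% and 65.8% (lymphoma and healthy L), 51.7% (lymphoma M-H), 64.0% and 82.5% (lymphoma L with M-H and the reverse) and 29.0% and 64.0% (healthy). At or above each list's median fold they were 60.1% and 58.4% in L, 49.2% and 86.5% in M-H, 60.8% and 79.2% within lymphoma and 24.9% and 58.6% within healthy. With equal list lengths they were 63.9% for lymphoma L, 69.0% and 69.3% in M-H, 71.4% and 71.2% within lymphoma and 39.3% and 39.2% within healthy, since cutting the longer list removes its weaker peaks.

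With equal lengths, M-H promoter genes were 1911 lymphoma-only and 513 healthy-only, and 1238 and 31 genes were so in both fractions. With 500 bp either side, 456 genes were healthy-only in L and 9 in both fractions. With absence over 5 kb, 11 were healthy-only in both. At a fold of at least 8, 416 (L) and 76 (M-H) were healthy-only, and 5 in both. At 12, lymphoma-only genes were 458 (L) and 1049 (M-H) and healthy-only 4 and 0. The lists differ in their fold values (medians 8.92 and 7.77 for lymphoma and healthy L, 10.1 and 8.14 for M-H), so a common cut-off removes more of the healthy lists and these counts say nothing on the difference between groups. The authors' flag gave 1808 and 2058 lymphoma-only and 281 healthy-only in L; it is a narrower definition. Lists with fewer lymphoma-only genes than the central 95% of random lists in L numbered 1 at a fold of at least 8 and 0 with 2 kb upstream to 500 bp downstream, against 2. The 1 at that fold was the developmental transcription factors (8 of 150), while the B-cell markers (percentile 3.0) and mutated genes (3.23) were no longer below the range. With absence over 5 kb the B-cell markers were at 3.71 and the housekeeping genes at 1.46. Among genes with a promoter peak, lists above that range were 0 (L) and 1 (M-H) and lists below it 1 (L) and 1 (M-H), in both cases the germline genes. The B-cell markers and mutated genes were inside it in both fractions, the latter with too few promoter peaks to fall below it.

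Promoter shares within 2 kb were 14.7% and 10.0% in L and 16.6% and 11.4% in M-H. At or above the median fold they were 11.3% and 6.73% in L and 14.0% and 8.69% in M-H, island or shore shares were 36.9% (lymphoma L), 53.7% and 46.5% (M-H), and the highest chromosome ratio in L was 1.38.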

Other observations

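The families and regions here, and the test of B-cell markers, were chosen after the data were seen. Collagen genes, which encode the main fibres of connective tissue, were often methylated at promoters in lymphoma only. Of 36 collagens, 14 were lymphoma-only and 0 healthy-only in L, and 13 of 10000 random lists held as many lymphoma-only genes. In M-H 18 were lymphoma-only and 1 was healthy-only, with 1 random list of 10000 holding as many. Potassium channels had 28 lymphoma-only and 1 healthy-only of 98 in L, and 34 and 3 in M-H, with 32 and 4 random lists holding as many lymphoma-only genes. The 3 healthy-only channels in M-H were also many, with 197 random lists holding as many. Solute carriers, a large group of membrane transporters, had 67 lymphoma-only of 256 in M-H (110 random lists) and 50 in L (1607 random lists). Numbered G protein-coupled receptors had 18 of 55 in M-H (221 random lists) and 10 in L (4663), and the 2 healthy-only in M-H were matched by 388 random lists. Zinc finger proteins (43 and 46 of 213) and ribosomal proteins (5 and 6 of 37) lay within the central 95% of random lists in both fractions. Olfactory receptors, which have few CpG-dense promoters, had 1 lymphoma-only and 3 healthy-only of 18 in L and 0 of either in M-H. Of 10000 random lists, 196 held as many healthy-only genes in L and 168 as few lymphoma-only genes in M-H. Against random lists drawn only from genes with a promoter peak, the collagens stayed above the central 95% in L (percentile 98.8) but not in M-H. Potassium channels (81.6 in L, 16.6 in M-H), solute carriers (88.6 in M-H) and numbered receptors (33.4 in M-H) were inside it, as were olfactory receptors (3.21 in L, 4.74 in M-H), and zinc finger proteins rose above it in M-H (99.3).

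In windows of 1 Mb, the largest surplus of lymphoma over healthy L peaks was on chromosome 18 from 47000001 to 48000000, around SHANK2 and CTTN, with 69 against 19 peaks. The window from 57000001 to 58000000 on chromosome 5, around PRDM16, SKI and PRKCZ, had 70 against 29 in L and 68 against 29 in M-H. A window on chromosome 27 from 2000001 to 3000000, with a cluster of keratin genes such as KRT7 and KRT78, had 66 against 27 in M-H. The largest surplus of healthy L peaks was on chromosome 5 from 72000001 to 73000000, within WWOX, a large tumour suppressor gene at a common fragile site in people, with 34 lymphoma and 56 healthy peaks. Copy number was not measured.

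Of the 4 B-cell markers with a promoter peak in 1 group only in L, 3 were healthy-only. Among all 32 members this count was at percentile 94.8 of random lists, inside the central 95%. A hypothesis is that non-B cells in the blood samples, in which B-cell promoters may be methylated, give these peaks. Of 10000 random draws of as many one-group genes, 145 held as many healthy-only genes in L, where 15.9% of one-group genes were healthy-only. In M-H 1 of 2 was healthy-only, and 528 draws held as many. These draws take the number of one-group genes as given, and that number is small because few B-cell markers were lymphoma-only (1 against a random mean of 5.44). With promoters of 500 bp either side 0 were lymphoma-only and 3 healthy-only, and at a fold of at least 8 in both lists 1 and 1. On the other side, 9 of 37 T-cell, 3 of 12 natural killer and 4 of 24 monocyte markers were lymphoma-only in either fraction, and in each fraction these lists lay within the central 95% of random lists. Of the 32 B-cell markers, 4 also stand in another list. The evidence rests on 4 genes, SPI1 is also a gene of myeloid cells, and the hypothesis stays open.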
